A study of Ovis aries with 4 samples.

How the data were processed

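Mammary gland tissue of 4 lactating ewes was measured by 10x droplet single-cell RNA sequencing, with 1 library per ewe. UMI counts per gene and barcode were used as deposited; they were made with Cell Ranger, with version 5.0.1 per the submitters' processing notes and version 7.2.0 per the file headers, and the notes also name STAR and Seurat 3.2.0. The genome build and annotation were not given in the sources used here. The deposited count files held 20150 genes and no barcode under 500 UMIs. Of these genes, 774 had a symbol and 19376 had an identifier alone. None of the identifiers matched the supplied reference table (0 matched), in which 762 of the 774 symbols were found, so names came from the deposited files and no coordinates were used. Named genes held 12.6% and 11.0% of the UMIs of the LH libraries and 12.0% and 13.1% of those of the LL libraries.

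Libraries were assigned to LH or LL by their titles, and replicate numbers were taken from the same titles. The tests, the gene lists, the cell type markers, the rule for naming genes and most of the other settings tried were chosen before the data were examined. Barcodes with over 20% mitochondrial UMIs, counted over 13 genes, were left out (102, 19, 94 and 145 barcodes of LH replicates 1 and 2 and LL replicates 1 and 2). Doublets were called per library with a Scrublet-type score on 2 simulated doublets per cell, which removed 472, 446, 651 and 581 cells (8.06%, 4.76%, 5.15% and 5.27%). Clusters in which over 50% of the cells were doublet calls were also left out. Counts were scaled to 10000 per cell, and 2000 variable genes gave 30 principal components, 20 neighbours and 33 Leiden clusters at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9). Milk protein, mitochondrial and ribosomal protein genes were left out of the variable genes where they had a symbol. This held for 8 of 16 listed milk protein genes and 7 of 77 listed ribosomal protein genes. Others with an identifier alone may have stayed among the variable genes. The later alternative without milk protein genes had the same limit.

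A cluster was given a type only with at least 3 fixed markers of that type at 20 CPM or more and at least 3 times the median level over clusters (with 5 CPM added to both), and where no other type had more markers among its leading 10 genes by fold. This ranking by leading genes was set after the data were seen, since clusters of other cells had luminal markers. Free casein RNA was taken as a possible source of these, which was not tested. Of 262 fixed markers 40 had a symbol, so many clusters stayed without a type and are given by number and leading genes. Both fixed lists of luminal markers were joined after the data were seen, as one of them had 2 named genes. The EDNRA/IGFBP7-high group was likewise formed after the data were seen, from clusters without a type that had EDNRA of at least 300 CPM, or both IGFBP7 of at least 1000 CPM and TIMP3 of at least 2000 CPM. Shares were given with exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared by exact two-sided permutation over 6 arrangements. They are shares of dissociated cells, not of tissue.

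For expression, counts were summed per library and cell group, for groups of at least 50 cells in each library. LL was compared with LH by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjusted p under 0.05 within a group. CPM values with a fold change used TMM-scaled library totals, whereas the levels of DCN, BGN and SPARC, of FABP4 in T cell-like cells, the comparison of MMP2 and TIMP2 between cell groups, and the levels of the ligand and receptor genes, of CXCR4, TGFB1 and FGF7 in the closing part, of all caseins together and of the gene without a symbol used unscaled totals. With 2 ewes per stage, p-values rest on few samples, and the precision of a level is that of the spread between ewes. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were measured, on log2 CPM with a prior count of 2, and list medians came from these values; an estimated correlation and fry were the alternatives. Of the 32 lists, those with fewer measured members were described by counts only. Genes without a symbol could not be matched to a list, so each list test covered only its members with a symbol.

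Genes to be named were the largest changes past the threshold with a symbol, at least 20 CPM on average, no overlap between stages and a level of at least 1 part in 4 of the highest group given a cell type. The EDNRA/IGFBP7-high group and numbered clusters were not counted there. TPM1 in luminal cells and FABP4 in macrophage-like cells thus qualified despite far higher levels in the EDNRA/IGFBP7-high group. Up to 10 rises and 10 falls were allowed per group, and 15 for fibroblast-like and luminal cells. Where fewer than 10 passed, the 10 of lowest p that met the other criteria were taken, along with members of the fixed lists. Values of both stages did not overlap for 44.8% of the named genes in the EDNRA/IGFBP7-high group, 33.7% in T cell-like cells, 40.7% in cluster 12, 42.7% in luminal cells, 32.3% in macrophage-like cells and 36.5% in fibroblast-like cells, where chance gives 33.3%. A ligand and receptor pair was called detected where each gene had 10 CPM or more in both libraries of a stage. The stage could differ between ligand and receptor.

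Alternatives were RLE size factors, DESeq2 1.42.0, the legacy quasi-likelihood fit, no filter on low counts, the replicate number as a block, doublet calls kept, at most 10% mitochondrial UMIs, at least 1000 UMIs, milk protein genes left out, clusters after centring within libraries, resolutions 0.5 and 2, equal numbers of cells, and each library left out in turn. The edgeR step was tested on simulated data with 200 changed genes per group, all of at least 20 CPM on average. A further 20 such genes per group were raised 2-fold in LL to test a list. They count among the calls as true changes, but not among the shares recovered. Genes of like abundance were given the same spread between libraries, whereas real genes differ in theirs. The shares recovered therefore do not give the power in the real data. PAEP in luminal cells, for example, changed 4.45-fold without passing (edgeR adjusted p = 0.10). Of the genes changed 4-fold, 100% were recovered in the EDNRA/IGFBP7-high simulation (11466 genes run), 100% for T cell-like (10087), 91.4% for cluster 12 (9507), 100% for luminal (13224), 77.8% for macrophage-like (8399) and 91.4% for fibroblast-like cells (9672). At 2-fold the recovered shares were 67.9%, 37.5%, 20.3%, 25.0%, 13.6% and 16.5% in the same order, and false calls were 19 of 206, 2 of 162, 5 of 142, 9 of 153, 9 of 128 and 2 of 136. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.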

Results

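Mammary gland tissue of 4 lactating ewes was profiled by droplet-based single-cell RNA sequencing, in which the transcripts of each captured cell carry a cell barcode and a unique molecular identifier (UMI). The series describes 2 ewes at peak lactation and 2 at late lactation, and its title names crosstalk of fibroblasts with immune cells and collagen dynamics as its subjects. The libraries were labelled LH replicates 1 and 2 and LL replicates 1 and 2. LL is the series' own abbreviation of late lactation, and the LH libraries were taken as peak lactation by elimination. Each library came from a different ewe, so n = 2 per stage throughout. The 4 libraries held 5955 and 9380 barcodes (LH replicates 1 and 2) and 12733 and 11178 barcodes (LL replicates 1 and 2). Total UMIs were 28015149 and 56178927 in LH and 60303230 and 65339993 in LL, with medians of 3294, 2992, 3036 and 2693 UMIs per barcode in the same order. After filtering, 5353, 8895, 11964 and 10430 cells were analysed. Of 20150 genes, 774 carried a gene symbol in the deposited files, and no collagen gene was among them, so collagen expression was not analysed here.

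The first comparison asked which cells made up the gland at each stage. Fibroblast-like cells, defined by DCN (decorin, a matrix proteoglycan), SFRP2 (a secreted WNT modulator), GSN (gelsolin, an actin-severing protein) and SERPINF1 (a secreted serpin), made up 2.25% ± 2.72 of cells in LH and 15.6% ± 4.52 in LL (SD, n = 2 ewes each). The values were 4.17% and 0.326% in the LH ewes and 18.8% and 12.4% in the LL ewes, so both LL libraries lay above both LH libraries. Macrophage-like cells, marked by C1QA (a complement component) and MRC1 (the mannose receptor), lay the other way, at 4.74% ± 0.706 in LH and 2.42% ± 1.21 in LL. Cluster 14, led by RELN (reelin, a secreted glycoprotein that lymphatic endothelium also makes), IGFBP5 and F8 (coagulation factor VIII), held 0.915% and 0.202% of cells in LH and 4.14% and 3.40% in LL. Cluster 12, led by IDO1, MMP7, CCN2 and IGFBP6, held 3.08% and 1.81% in LH and 3.56% and 3.74% in LL.

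The most abundant populations did not separate by stage. T cell-like cells, marked by CD3E, CD247 and LCK of the T cell receptor signalling machinery, made up 71.0% of LH replicate 1 and 14.8% of LH replicate 2, against 18.5% and 18.3% in LL. A group led by EDNRA (the endothelin A receptor) and IGFBP7 (a secreted IGF-binding protein abundant in vascular cells) held 8.52% and 41.8% in LH and 30.5% and 32.4% in LL. CNN1 (calponin 1, a smooth muscle protein), TPM1, AVPR1A and AGTR1 (receptors for vasopressin and angiotensin) were among its leading genes. CNN1 was a fixed marker of myoepithelium here. Of the fixed markers, 1 of pericytes or vascular smooth muscle and 2 of myoepithelium had a symbol. These were too few to assign a cell type or to tell these types apart. Luminal epithelium-like cells, marked by PAEP (the gene of beta-lactoglobulin, the main whey protein of ruminants), EPCAM and CLDN4, held 5.40% and 31.6% in LH and 8.54% and 25.4% in LL. Cluster 11, led by the endothelial adhesion genes SELP and SELE and by KDR (a VEGF receptor), held 7.81% of LL replicate 1 and between 0.0560% and 1.07% of the other libraries. Exact binomial 95% intervals were narrow beside these differences between ewes; for fibroblast-like cells they were 3.65% to 4.74% and 0.218% to 0.468% in LH and 18.1% to 19.5% and 11.8% to 13.1% in LL, and they covered counting error only.

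In exact two-sided permutation tests the smallest p that 2 ewes against 2 allow is 0.33, which the fibroblast-like, macrophage-like, cluster 12 and cluster 14 shares reached (exact p = 0.33 each). No share could therefore pass 0.05 in that test. T cell-like cells filled 71.0% of LH replicate 1 (3802 of 5353 cells), which lowers all other shares of that library. T cell-like cells numbered 1315 of 8895 in LH replicate 2 and 2214 of 11964 and 1903 of 10430 in LL. Cluster 12 held 165 and 161 cells in LH and 426 and 390 in LL. Among cells that were not T cell-like, its share in LH replicate 1 lay above both LL libraries, so it did not separate by stage there. Fibroblast-like cells (223 and 29 in LH, 2252 and 1297 in LL) still lay higher in both LL libraries. In that comparison LH replicate 1 lay close below LL replicate 2, and no test was run on it. An edgeR test of cell counts, which has no such lower limit, gave a log2 ratio of 2.80 for fibroblast-like cells (adjusted p = 0.298) and 2.76 for cluster 14 (adjusted p = 0.298), and for macrophage-like cells it gave -0.97 (adjusted p = 0.935). The macrophage-like difference of -2.32 percentage points was -1.46 without LL replicate 2, and with cells of at least 1000 UMIs it was -1.46 as well, where LH replicate 1 (3.30%) lay below LL replicate 1 (3.37%; exact p = 0.667). The cluster 12 difference of 1.20 percentage points was 0.568 without LH replicate 2 and 1.84 without LH replicate 1. Without LH replicate 1, the difference of T cell-like cells turned from -24.5 to 3.59 percentage points and that of the EDNRA/IGFBP7-high group from 6.27 to -10.4. The luminal difference of -1.55 percentage points turned to 11.6 without LH replicate 2 and to 6.86 without LL replicate 1.

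**Figure D1:**
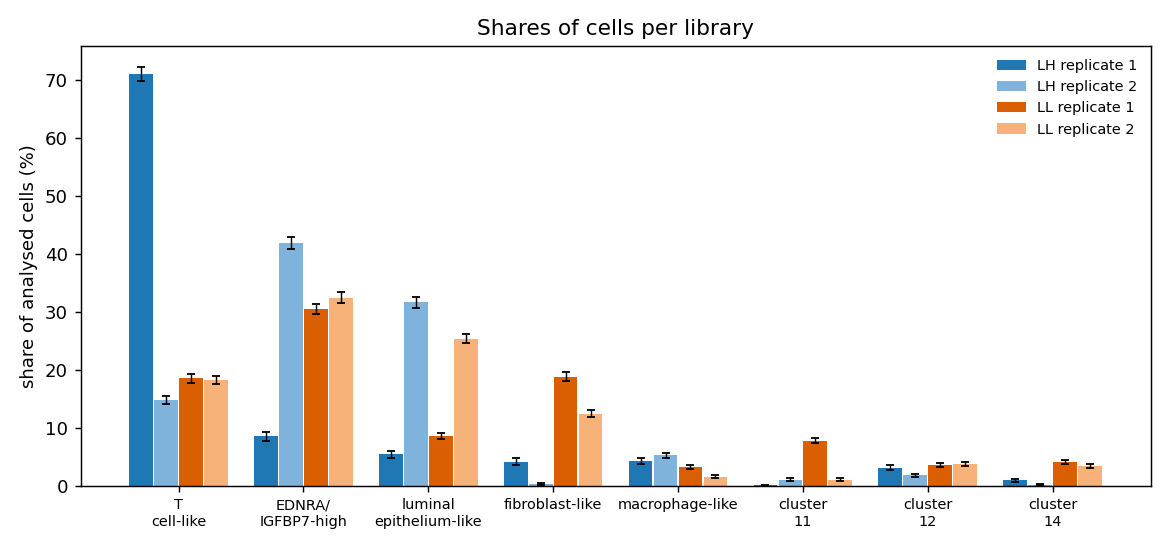
Share of analysed cells (%, vertical axis) in 8 cell groups for each library, with blue bars for LH and orange bars for LL and error bars giving exact binomial 95% intervals. T cell-like cells reach 71.0% in LH replicate 1, and fibroblast-like cells reach 18.8% and 12.4% in LL against 4.17% and 0.326% in LH.

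The next comparison asked how the luminal epithelium differed between the stages. PAEP had a mean of 756 CPM (counts scaled to a common library total) ± 4.79 in LH and 3363 ± 42.4 in LL (SD, n = 2), a log2 change of 2.15 ± 0.20 (SE; edgeR adjusted p = 0.10). ATP1B1, the beta subunit of the sodium pump, stood at 205 ± 19.3 CPM in LH and 521 ± 36.4 in LL (log2 1.35; edgeR adjusted p = 0.166). SPP1, which encodes osteopontin, a phosphoprotein secreted into milk, lay the other way with 4468 ± 693 CPM in LH and 1235 ± 260.2 in LL (log2 -1.86; edgeR adjusted p = 0.178). SERPINB1, an intracellular inhibitor of neutrophil proteases, was at 499 ± 51.3 and 166 ± 22.9 CPM (log2 -1.58; edgeR adjusted p = 0.154). MMP7, an epithelial matrix metalloproteinase, was at 119.6 ± 20.8 and 23.6 ± 12.6 CPM (log2 -2.35; edgeR adjusted p = 0.270). None of these named genes passed the edgeR threshold, whereas DESeq2 gave adjusted p of 6.6e-23 for PAEP, 5.8e-07 for ATP1B1, 2.4e-09 for SPP1, 5.6e-08 for SERPINB1 and 3.9e-06 for MMP7.

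Among the remaining named genes of luminal cells, CPT1A, which carries long-chain fatty acids into mitochondria, had 51.5 CPM in LH and 22.6 in LL (log2 -1.18; edgeR adjusted p = 0.292), and ABHD5, the coactivator of the triglyceride lipase ATGL, had 138 and 70.7 (log2 -0.96; edgeR adjusted p = 0.254). The clock repressor CRY2 (log2 0.96) and the actin-binding tropomyosin TPM1 (log2 -1.15) completed the set together with CSN2, described with the milk proteins. In edgeR 1 of 13432 genes passed in luminal cells, 1334 had an unadjusted p under 0.05, and DESeq2 called 285, of which 128 were higher in LL and 157 lower. The called gene, ENSOARG00000002980, had no symbol. Cluster 2, led by LTF and PAEP, held 56.2% and 78.7% of the luminal cells of the LL ewes, while cluster 5, led by SPP1 and SERPINB1, held 59.5% and 66.8% of those of the LH ewes, so these values also compare different clusters of the class. The edgeR count was 0 without either LH library, 12 without LL replicate 1 and 189 without LL replicate 2.

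**Figure D2:**
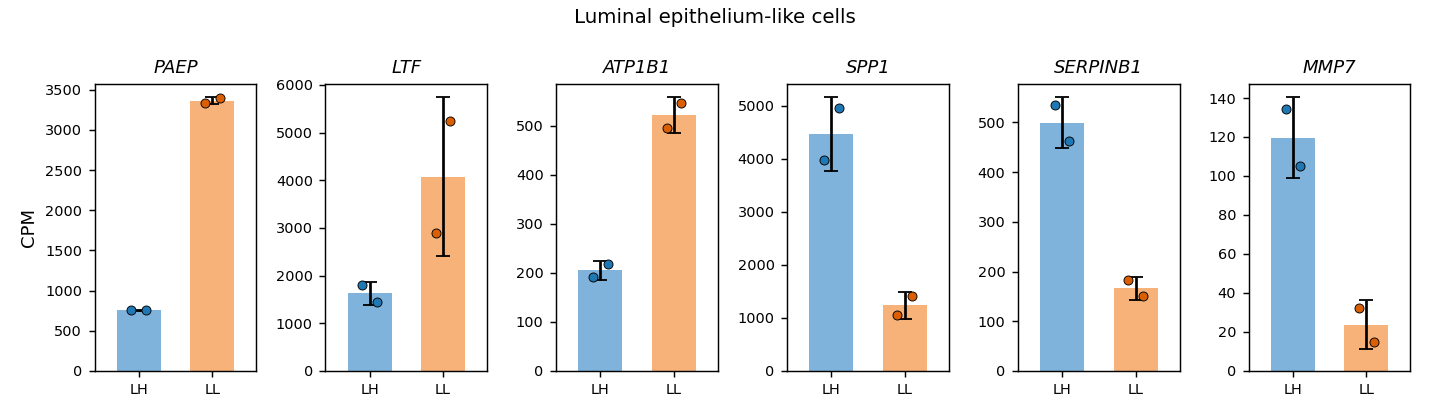
Expression (CPM, vertical axis from 0) of 6 named genes in luminal epithelium-like cells; bars give the mean of 2 ewes, error bars the SD and points the libraries. PAEP lies at 756 CPM in LH and 3363 in LL, and SPP1 at 4468 and 1235.

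Of the gene lists fixed in advance, the measured involution markers and oxidative phosphorylation genes were higher in LL in luminal cells. They were 6 of 31 and 7 of 72 listed genes, as the others had no symbol, so they do not stand for the whole lists. The 6 measured involution markers had a median log2 change of 0.66 (camera adjusted p = 0.0170; adjusted p = 0.810 with an estimated correlation). LTF (lactoferrin, an iron-binding milk protein that increases as milk removal stops) had 1626 ± 249 CPM in LH and 4071 ± 1668 in LL, with a log2 change of 1.32. IGFBP5, which is made by the involuting gland, had 24.4 ± 15.6 and 54.3 ± 14.4 CPM (log2 1.11), and 3 of the 6 had both LL libraries above both LH libraries. The 7 measured oxidative phosphorylation genes had a median log2 change of 0.37 (camera adjusted p = 0.0170; adjusted p = 0.810 with an estimated correlation). ATP5MC1 (log2 0.76) and ATP5PO (log2 0.37), both of ATP synthase, and NDUFA12 (log2 0.51) of complex I were examples, and 6 of the 7 had both LL libraries above both LH libraries. In edgeR 0 members of either list passed over all genes or adjusted over the list alone; 1 and 2 members had an unadjusted p under 0.05, and DESeq2 called 1 and 0. The involution list had an adjusted p of 0.0863 with milk protein genes left out, and without single libraries it ran from 0.0097 to 0.136 (over 0.05 without LH replicate 1, LL replicate 1 or LL replicate 2); oxidative phosphorylation ran from 0.0205 to 0.331 (over 0.05 without LH replicate 1 or LL replicate 2).

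Milk protein, milk fat and lactose genes were described as the study concerns lactation. Caseins were scarce in the data: casein transcripts numbered 28 and 228 UMIs in the LH libraries and 25340 and 686 in the LL libraries, and LALBA, which encodes alpha-lactalbumin, numbered 1, 0, 266 and 3 UMIs. In luminal cells all caseins together stood at 1.85 and 6.01 CPM in LH and at 1497 and 17.3 CPM in LL, so LL replicate 1 held the main part. CSN2 (beta-casein) had 0 and 0.173 CPM in LH and 135 and 11.4 CPM in LL. The 4 measured milk protein genes (CSN2, CSN3, PAEP and LTF) all had both LL libraries above both LH libraries. In edgeR 0 of them passed over all genes, 4 passed adjusted over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 3. Milk fat genes were mixed: 7 of 13 had a log2 change above 0, among them ME1 (malic enzyme, a source of NADPH; log2 1.02) and ACACA (acetyl-CoA carboxylase; log2 0.52), while LPL was at log2 -1.46 (camera adjusted p = 0.593; edgeR 0 passed, 4 with an unadjusted p under 0.05, DESeq2 0). B4GALT1, the catalytic partner of alpha-lactalbumin in lactose synthase, had 68.5 and 70.7 CPM in LH and 49.4 and 51.8 CPM in LL (log2 -0.46; edgeR adjusted p = 0.455).

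In the EDNRA/IGFBP7-high cells FABP4 rose. FABP4, a fatty acid-binding protein of adipocytes and capillary endothelium, increased from 69.7 ± 13.6 CPM in LH to 435 ± 55.0 in LL (SD, n = 2), a log2 change of 2.66 ± 0.21 (SE; edgeR adjusted p = 0.0153). Its edgeR adjusted p was 0.130 without LL replicate 1 and 0.0834 without LL replicate 2, with log2 changes of 2.52 and 2.78. FABP4 and CDKN1A were among the leading genes of cluster 17, which held 1.10% and 1.16% of the group in LH and 15.8% and 5.56% in LL; without that cluster, a comparison added after the data were seen, FABP4 had a log2 change of 2.47 (edgeR adjusted p = 0.0149). Cluster 7, led by FABP4, held 7.46% and 18.3% in LH and 13.96% and 24.3% in LL. BTG2 and CDKN1A, both inhibitors of cell cycle progression, had 573 and 341 CPM in LH and 1201 and 759 CPM in LL (log2 1.07 and 1.15; edgeR adjusted p = 0.141 and 0.174). ICAM1, the leukocyte adhesion molecule, had 31.3 ± 1.61 and 76.7 ± 21.2 CPM (log2 1.30; edgeR adjusted p = 0.187). TPM1, which stabilises actin filaments of contractile cells, had 1929 ± 5.52 and 1076 ± 63.8 CPM (log2 -0.84; edgeR adjusted p = 0.192). Clusters 0 and 19, which both had TPM1 among their leading genes, held 52.4% and 35.7% (cluster 0) and 16.2% and 10.0% (cluster 19) of the group in LH, against 31.4% and 32.7% and 3.32% and 3.61% in LL, so the TPM1 values also compare different proportions of these clusters. FGF7, a stromal growth factor for epithelium, had 112 and 68.9 CPM (log2 -0.71; edgeR adjusted p = 0.297).

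In these cells the measured part of the matrix degradation list, 10 of 36 genes, was higher in LL. Its median log2 change was 0.76 (camera adjusted p = 7.4e-05, or 0.728 with an estimated correlation). TIMP3, a matrix-bound inhibitor of metalloproteinases, had 1641 ± 423 CPM in LH and 2994 ± 244 in LL (log2 0.87; edgeR adjusted p = 0.304), and TIMP2, another inhibitor, had 40.4 and 72.8 CPM (log2 0.82). PLAU, the urokinase-type plasminogen activator, had 83.1 and 157 CPM (log2 0.87). TIMP3 was among the leading genes of clusters 7 and 17 (4240 and 4326 CPM), and PLAU of cluster 7 (422 CPM). Cluster 17 held more of the group in LL, while the values of cluster 7 overlapped between stages, so these levels also compare different proportions of clusters. TIMP3 was also among the genes that admitted clusters to the group. In edgeR 0 of the 10 passed over all genes, 4 passed adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 2. MMP2 and TIMP2 were far more abundant in fibroblast-like cells (476 and 1769.5 CPM, against 1.97 and 56.6 CPM here), and without the 5 members over 4 times higher in fibroblast-like cells the median was 0.56 and the adjusted p 0.0853. The measured part of the dissociation and immediate early response list, 7 of 32 genes, was higher as well. Its median log2 change was 0.53 (camera adjusted p = 0.0026, or 0.728 with an estimated correlation). ZFP36, which destabilises cytokine transcripts, was at log2 0.74 and EGR1 at log2 0.52. For that list 0 genes passed in edgeR over all genes, 3 passed adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called 2, and its adjusted p was 0.0555 without LL replicate 1.

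Inflammatory genes went both ways in the EDNRA/IGFBP7-high cells. NFKBIA, the inhibitor induced by NF-kappa-B, had 334 and 408 CPM in LH and 855 and 1184 CPM in LL (log2 1.46), and PTGS2, the inducible cyclooxygenase, had 20.7 and 17.9 against 64.2 and 38.6 CPM (log2 1.44). PTGS2 was among the leading genes of cluster 17 (189 CPM), a larger part of the group in LL, and of fibroblast-like cluster 4 (307 CPM). Neither the proportion of cluster 17 nor free RNA of fibroblast-like cells was excluded for its difference. IL18, an interferon-inducing cytokine, had 68.3 and 90.3 against 28.2 and 27.7 CPM (log2 -1.52). Of the 9 measured cytokine and chemokine genes, 0 passed in edgeR over all genes, while 4 rose and 1 fell adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 4 (camera adjusted p = 0.125). In edgeR 6 of 11696 genes passed in this group, 3 higher and 3 lower in LL; 1156 had an unadjusted p under 0.05 and DESeq2 called 103. The edgeR count was 51 with equal numbers of cells per library, 71 without LH replicate 2 and 1 without either LL library.

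DCN was by far most abundant in fibroblast-like cells, where it stood at 16990 ± 2117 CPM in LH and 17040 ± 1631 in LL. BGN (biglycan) stood at 106 ± 1.62 and 98.7 ± 11.5 CPM there and at 76.5 ± 31.1 and 81.9 ± 9.51 CPM in the EDNRA/IGFBP7-high group. SPARC, a collagen-binding glycoprotein, stood at 600.2 ± 276 and 527 ± 202 CPM, so none of the 3 genes differed between stages by more than the spread between ewes (edgeR 0 passed, 0 with an unadjusted p under 0.05, DESeq2 0). Low DCN values in other cell groups were not read as expression or as a difference between stages there, since free RNA of fibroblast-like cells, more frequent in both LL libraries, can give them. They stood at 15.3 and 2.30 CPM in T cell-like cells of LH and at 92.7 and 45.6 CPM in those of LL, and at 13.9 and 5.20 against 111 and 58.0 CPM in the EDNRA/IGFBP7-high group. SPARC had 135 ± 10.2 and 189.7 ± 37.0 CPM in the EDNRA/IGFBP7-high group. There 2 of the 3 matrix genes (DCN and SPARC) passed adjusted over the list alone, edgeR called 0 over all genes, 2 had an unadjusted p under 0.05 and DESeq2 called 1. Free RNA was not excluded for DCN. For SPARC, fibroblast-like cells are argued against as the source. DCN reached only 111 CPM here against 17040 there, and SPARC stood at 527 CPM there, so so small a share would bring little SPARC. Free RNA of other cells was not excluded.

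In fibroblast-like cells MX1, an interferon-induced antiviral GTPase, had 15.5 and 20.01 CPM in LH and 57.8 and 72.3 CPM in LL (log2 2.00; edgeR adjusted p = 0.795), and ISG15, an interferon-induced ubiquitin-like protein, had 0 CPM in both LH libraries and 21.7 and 14.4 CPM in LL. LH replicate 2 held 93018 UMIs in these cells, of which 2 were of MX1 and 0 of ISG15, both under the floor of 3 counts, so that library told little about either gene. SERPINF1 had 1696 ± 361 and 753 ± 72.2 CPM in these cells (log2 -1.16; edgeR adjusted p = 0.820), and it led cluster 4, which held 87.0% and 79.3% of them in LH and 66.3% and 70.9% in LL. Fibroblast-like cells had BMP4, a morphogen of the TGF-beta family, at 49.1 and 88.0 CPM (log2 1.04), and TIMP1 at 1102 and 1411 CPM in LH against 865 and 728 CPM in LL (log2 -0.65).

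**Figure D3:**
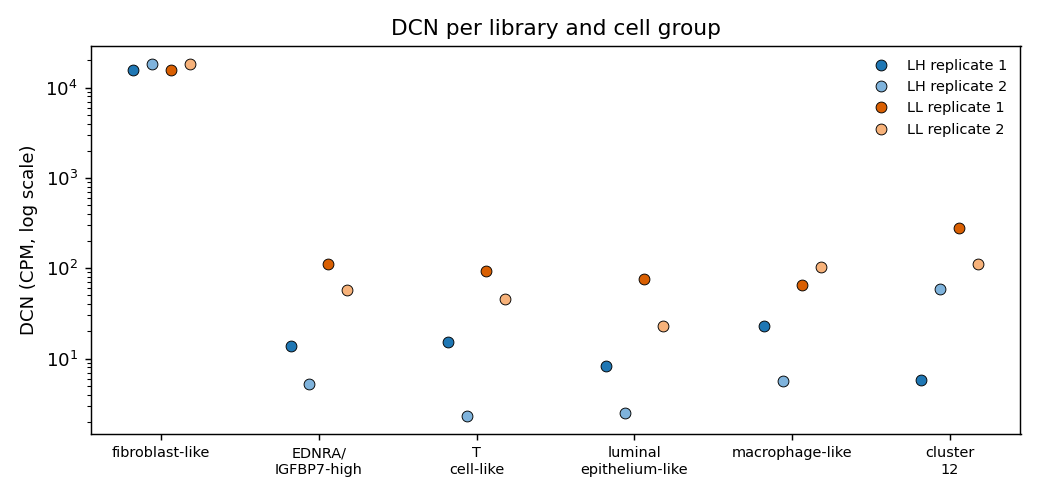
DCN expression (CPM, log scale) per library in 6 cell groups, with blue points for LH and orange points for LL. Fibroblast-like cells lie at a mean of 16990 CPM in LH and 17040 in LL, and T cell-like cells at 15.3 and 2.30 CPM in LH and 92.7 and 45.6 CPM in LL.

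In fibroblast-like cells edgeR called 0 of 9962 genes; 561 had an unadjusted p under 0.05 and DESeq2 called 7. This comparison was added after the data were seen, as LH replicate 2 held 29 fibroblast-like cells, below the minimum of 50. Of the 4 measured interferon response genes, 0 passed over all genes in edgeR, 2 passed adjusted over the list alone (MX1 and ISG15, both under the floor of 3 counts in LH replicate 2), 2 had an unadjusted p under 0.05 and DESeq2 called 0. Matrix degradation and TGF-beta response genes had camera adjusted p of 0.840 and 0.926 (0.885 and 0.933 with an estimated correlation). The edgeR count was 1 without LH replicate 1 and 4 without LH replicate 2.

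In T cell-like cells CTLA4 had the lowest p among the named genes; it encodes an inhibitory receptor of activated and regulatory T cells. It had 55.0 and 92.9 CPM in LH and 22.7 and 19.6 CPM in LL, a log2 change of -1.79 ± 0.29 (SE; edgeR adjusted p = 0.322; DESeq2 adjusted p = 3.9e-04). PYGB, a glycogen phosphorylase, had 40.5 and 21.7 CPM (log2 -0.91; edgeR adjusted p = 0.551), and SLC25A20, the mitochondrial carnitine carrier, 28.7 and 13.2 CPM (log2 -1.12; edgeR adjusted p = 0.587). ABHD5 and CPT1A, which were also lower in LL in luminal and macrophage-like cells, had 95.1 and 85.0 CPM in LH. In LL they had 47.6 and 42.5 CPM (log2 -1.01 and -1.01, edgeR adjusted p = 0.656 and 0.671). SLAMF1, a receptor of activated lymphocytes, lay the other way with 74.9 and 126 CPM (log2 0.74; edgeR adjusted p = 0.704). Cluster 13, led by SLAMF1, held 7.44% and 7.91% of the T cell-like cells in LH and 20.1% and 17.6% in LL, and cluster 6, led by CD3E, 25.2% and 44.9% against 13.7% and 17.4%, so these values also compare different proportions of clusters. CTLA4 was among the leading genes of cluster 8, whose shares overlapped between stages (20.7% and 19.7% in LH, 16.1% and 21.9% in LL). Of the 8 measured T cell effector genes, 0 passed over all genes in edgeR, 1 fell adjusted over the list alone (CTLA4), 2 had an unadjusted p under 0.05 and DESeq2 called 1. IFNG and TNF were abundant without a difference beyond the spread between ewes: IFNG had 1284 and 867 CPM in LH and 1222 and 1139 CPM in LL, and TNF 445 and 247 against 306 and 232 CPM. In edgeR 1 of 10318 genes passed, 672 had an unadjusted p under 0.05 and DESeq2 called 39. The edgeR count was 3 without LH replicate 1, 2 without LL replicate 1 and 22 without LL replicate 2.

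In macrophage-like cells no gene with a symbol passed the edgeR threshold, and the named genes lay in both directions. FABP4 had 2.08 ± 2.95 CPM in LH, with 0 in LH replicate 1, and 45.0 ± 25.4 in LL (log2 4.15; edgeR adjusted p = 0.997; DESeq2 adjusted p = 0.0206). It had 0 and 2.88 CPM in T cell-like cells of LH and 9.24 and 3.74 CPM in those of LL, and it was abundant in the EDNRA/IGFBP7-high group of LL, so RNA of other cells was not excluded as a source in macrophage-like cells. ABHD5 had 114 ± 5.99 CPM in LH and 40.1 ± 1.65 in LL (log2 -1.50; edgeR adjusted p = 0.922), CPT1A 90.8 ± 14.9 and 43.6 ± 0.777 CPM (log2 -1.06; edgeR adjusted p = 0.997), and FCGRT, which encodes the neonatal Fc receptor, 80.0 ± 9.86 and 28.9 ± 4.62 CPM (log2 -1.45; edgeR adjusted p = 0.997). IDO1, a tryptophan-degrading enzyme, had 18.2 ± 7.32 and 112 ± 83.3 CPM (log2 2.62; edgeR adjusted p = 0.997). Of the 10 measured milk fat genes, 4 had a log2 change above 0 and 1 (FABP4, with that limit) passed adjusted over the list alone; edgeR called 0 over all genes, 2 had an unadjusted p under 0.05, DESeq2 called 1, and the camera adjusted p was 0.770. Of the 10 measured genes of classical activation, 2 had a log2 change above 0, and IL1B, TNF and IL1A varied more between ewes of a stage than between stages; edgeR called 0, 0 had an unadjusted p under 0.05, DESeq2 called 0, and the camera adjusted p was 0.250. In edgeR 1 of 8725 genes passed, 380 had an unadjusted p under 0.05 and DESeq2 called 9. Cluster 18, led by CXCL8 and IL1A, held 50.7% and 37.3% of the macrophage-like cells in LH and 82.1% and 70.7% in LL, and cluster 21, led by C1QA, held the others. The edgeR count was 0 without LH replicate 1, 2 without LH replicate 2 and 9 without LL replicate 2.

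In cluster 12 no gene with a symbol passed the edgeR threshold. Among the named genes, IGFBP6, a binding protein of IGF2, had 2093 ± 279 CPM in LH and 509.6 ± 230.4 in LL (log2 -2.04; edgeR adjusted p = 0.145), and SPP1 had 1209 ± 416 and 277 ± 150.3 CPM (log2 -2.12; edgeR adjusted p = 0.171). CFTR, the chloride channel, had 52.9 ± 37.1 and 1.93 ± 0.624 CPM (log2 -4.81; edgeR adjusted p = 0.117), and SLC12A2, the sodium-potassium-chloride cotransporter, 475 ± 122 and 196 ± 50.4 CPM (log2 -1.28; edgeR adjusted p = 0.205). ID3, a transcriptional inhibitor induced by BMP signalling, lay the other way with 63.3 ± 17.9 and 142 ± 26.3 CPM (log2 1.19; edgeR adjusted p = 0.222). In edgeR 5 of 9781 genes passed, 3 higher and 2 lower in LL and none with a symbol; 1030 had an unadjusted p under 0.05 and DESeq2 called 118. With the replicate number as a block edgeR called 32 genes, of which 2 had a symbol. Without the filter on low counts it called 10, of which 0 had a symbol. The edgeR count was 0 to 1 when a library was left out.

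The comparison of fibroblast and immune signalling genes covered 3 of 71 fixed ligand and receptor pairs, for which both genes had symbols. A gene counted as detected where both libraries of a stage reached 10 CPM. By that rule 6 directed pairs were detected: TNF of T cell-like and of macrophage-like cells with its receptor gene TNFRSF1A in fibroblast-like cells, and ICAM1 of fibroblast-like cells with the integrin genes ITGB2 and ITGAL of T cell-like and macrophage-like cells. Of these, 1 (ICAM1 with ITGAL of T cell-like cells) remained at 50 CPM. In fibroblast-like cells ICAM1 had 65.8 and 43.0 CPM in LH and 59.9 and 51.3 CPM in LL, and ITGAL in T cell-like cells had 200.4 and 129 against 139 and 129.6 CPM. TNFRSF1A in fibroblast-like cells had 12.2 and 21.5 CPM in LH and 9.54 and 5.31 CPM in LL (log2 -0.89; edgeR adjusted p = 0.887). It reached 10 CPM in LH only, and its value in LH replicate 2 came from 2 UMIs, under the floor of 3 counts, so its detection there was not secure. In edgeR 0 of the 8 tests of a gene in a cell type passed, with a lowest value of 0.547 adjusted over the list alone.

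A gene without a symbol, ENSOARG00000002980, was higher in LL in all 5 cell groups planned for testing, and it was singled out after its values were seen. It had 8 and 21 UMIs in the whole LH libraries and 8511 and 12892 UMIs in the LL libraries. In luminal cells it stood at 0.555 and 0.433 CPM in LH and 197 and 225 CPM in LL, and in T cell-like cells at 0.25 and 0 against 58.6 and 56.9 CPM. In fibroblast-like cells, where edgeR called no gene, it had 0 CPM in both LH libraries and 125 and 140.3 CPM in LL. It was the gene called in luminal, T cell-like and macrophage-like cells, and it was among the called genes of the EDNRA/IGFBP7-high group and of cluster 12. A search was made for genes at 10 CPM or more in a pair of libraries and at most 1 CPM in the others. It required at least 4 of the 6 groups, and gave this gene for the LL pair and 0 genes for every other pair. A difference between these ewes other than the stage cannot be told apart from the stage here.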

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

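The tests of the explanations weighed here, and the comparison of opposite changes in pairs of cell groups, were chosen only after the values were seen.

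Named genes that lay in opposite directions in a pair of cell groups were compared by an edgeR interaction of stage and group with the library as a block, adjusted over the 6 comparisons. TSPO, a cholesterol transporter of mitochondria, had log2 changes of -1.05 in cluster 12 and 0.35 in the EDNRA/IGFBP7-high group, a difference of -1.39 (adjusted p = 0.0025; 0.267 over all genes). ID3 had 1.19 and -0.76 in the same groups, a difference of 1.94 (adjusted p = 8.5e-04; 0.126 over all genes). B4GALT1 had -0.46 in luminal cells and 0.76 in the EDNRA/IGFBP7-high group, a difference of -1.20 (adjusted p = 0.0060; 0.435 over all genes). Against T cell-like cells, with 0.54, the luminal difference of B4GALT1 was -0.99 (adjusted p = 0.0062; 0.455 over all genes). CDKN1A had -0.79 in macrophage-like cells and 1.15 in the EDNRA/IGFBP7-high group, a difference of -1.94 (adjusted p = 0.0025; 0.821 over all genes). TMEM154 had 1.21 in macrophage-like cells and -0.58 in luminal cells, a difference of 1.71 (adjusted p = 0.0133; 0.781 over all genes). The genes were picked for their opposite directions, so the values adjusted over the 6 comparisons are not independent evidence.

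Casein RNA was abundant in luminal cells of LL replicate 1 alone, at 1497 CPM against 17.3 CPM in LL replicate 2. Free milk RNA in the droplets would give cell types a like level, but luminal cells of that library had 12.7 times the casein CPM of its T cell-like cells (118 CPM), which argues against free RNA as the source of the luminal level. Loss of secretory cells to the mitochondrial filter is argued against by 0 casein UMIs in the removed barcodes of the other 3 libraries. An exchange of labels with an LH library is argued against by PAEP, which in LL replicate 1 was 4.39 times the higher LH library, while the LL libraries differed 1.02 times, with LL replicate 2 the higher. A difference between ewes in milk synthesis or in the capture of secretory cells may remain and was not tested.

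The matrix degradation list, with 10 of its 36 genes measured, was higher in LL in the EDNRA/IGFBP7-high cells (camera adjusted p = 7.4e-05, or 0.728 with an estimated correlation). Free RNA of fibroblast-like cells, more frequent in LL, might add to it: without the 5 members over 4 times higher in fibroblast-like cells the adjusted p was 0.0853 and the median log2 change went from 0.76 to 0.56, with 5 members left instead of 10, which keeps this explanation open. Cells of cluster 17, which made up 15.8% and 5.56% of the group in LL and 1.10% and 1.16% in LH, are argued against as the whole cause, as the adjusted p without them was 1.2e-04. Leaving out cluster 7, which had TIMP3 and PLAU among its leading genes, was not tried. A response to tissue dissociation that differed between stages stays open, as the dissociation list had a median log2 change of 0.53 in the same cells. An effect of the stage itself also stays open and was not tested.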

How the results depend on the processing

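Tests in fibroblast-like cells, without cluster 17 and without members high in fibroblast-like cells were chosen only after the data were seen. With 2 ewes per stage, leaving out a library leaves 1, which edgeR assumes to vary like the other stage; shares are then given without a test.

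Counts of genes past the test depended on the tool: DESeq2 gave 103 in the EDNRA/IGFBP7-high group (edgeR 6), 39 in T cell-like cells (1), 118 in cluster 12 (5), 285 in luminal (1), 9 in macrophage-like (1) and 7 in fibroblast-like cells (0). Equal numbers of cells gave 51 in the EDNRA/IGFBP7-high group, 3 in luminal and 2 in macrophage-like cells. Without the filter on low counts the counts were 2 in T cell-like cells, 10 in cluster 12, 5 in luminal and 2 in macrophage-like cells. The legacy fit gave 2 in luminal, 2 in macrophage-like and 1 in fibroblast-like cells. Cluster 12 had 3 at 10% mitochondrial UMIs. Macrophage-like cells had 2 with RLE, 2 at 1000 UMIs and 4 at resolution 0.5. With single libraries left out the ranges were 1 to 71 in the EDNRA/IGFBP7-high group, 1 to 22 in T cell-like cells, 0 to 1 in cluster 12, 0 to 189 in luminal, 0 to 9 in macrophage-like and 0 to 4 in fibroblast-like cells. The cause was not tested.

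The replicate number as a block gave 5 genes in T cell-like cells, 32 in cluster 12, 3 in luminal and 3 in macrophage-like cells, 5 in the EDNRA/IGFBP7-high group, 0 in fibroblast-like cells and 4 lists in the EDNRA/IGFBP7-high group. Deviations of libraries sharing a number correlated at 0.105, -0.0806, 0.112, -0.0526, 0.294 and 0.0268 across genes (EDNRA/IGFBP7-high, T cell-like, cluster 12, luminal, macrophage-like and fibroblast-like), so with 2 pairs the numbers were not taken to pair the ewes.

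Lists past the test numbered 2 in the EDNRA/IGFBP7-high group and 2 in luminal cells, and 0 in both with an estimated correlation or fry; luminal cells had 1 with milk protein genes left out. Without single libraries they ranged from 1 to 5 in the EDNRA/IGFBP7-high group, 1 to 3 in T cell-like cells, 0 to 2 in cluster 12, 1 to 2 in luminal, 0 to 3 in macrophage-like and 0 to 1 in fibroblast-like cells. With an estimated correlation the adjusted p was 0.728 for the dissociation and matrix degradation lists and 0.810 for the involution and oxidative phosphorylation lists; with fry it was 0.224, 0.331, 0.409 and 0.409. Matrix degradation had 0.0853 without members high in fibroblast-like cells, and involution 0.0863 without milk protein genes. Without single libraries the adjusted p ran from 0.0067 to 0.0555 for dissociation, 5.6e-08 to 0.0339 for matrix degradation, 0.0097 to 0.136 for involution and 0.0205 to 0.331 for oxidative phosphorylation. Pairs of ligand and receptor went from 6 to 1 at 50 CPM.

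The difference of shares reversed without LH replicate 1 for T cell-like cells (3.59; range -52.7 to 3.59) and the EDNRA/IGFBP7-high group (-10.4; range -10.4 to 22.9), and for luminal cells without LH replicate 2 (11.6) or LL replicate 1 (6.86; range -14.7 to 11.6). That of macrophage-like cells ranged from -3.17 to -1.46 and was -1.46 at 1000 UMIs. Of 1011 values of 60 named gene and group pairs, 1011 kept their direction, 36 passed only in an alternative (23 with DESeq2) and 2 lost the call (FABP4 without either LL library). The 60 pairs had been chosen for values that did not overlap between stages, so leaving out a library could hardly reverse their direction. Most other alternatives used largely the same counts. The kept directions are therefore not independent evidence. Collagen alternatives were not run, as no collagen gene had a symbol.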

Other observations

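The clock genes, the small clusters and the tests on them given here were chosen only after their values were seen.

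Several small clusters differed between libraries. Cluster 30, led by TPSB2 (a mast cell tryptase), FCER1A (part of the IgE receptor) and GATA1, held 87 and 15 cells in the LL libraries (0.727% and 0.144%) and 0 cells in both LH libraries, which allows shares of up to 0.0689% and 0.0415% by the exact interval; the edgeR log2 ratio was 8.32 (adjusted p = 0.0546), a fitted value that depends on the prior count. Cluster 32, led by the interferon-induced genes MX2, ISG15, MX1 and CXCL10, held 0 and 41 cells in LH and 0 and 3 cells in LL. Cluster 24, led by the cell cycle kinases CDK1 and AURKA, held 0.673% and 1.27% in LH and 0.334% and 0.920% in LL. T cell-like cells held TGFB1 at 317 and 173 CPM in LH and 151 and 224 CPM in LL, and the homing receptor gene CXCR4 at 119 and 124 against 145 and 137 CPM. Fibroblast-like cells held FGF7 at 272 and 344 CPM in LH and 165 and 217 CPM in LL.

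DBP, HLF, TEF and NR1D1, which are driven by the circadian clock, were not a fixed list and were not tested as one. They gave 19 measured values over the 6 groups, all from the same 4 ewes, of which 18 had a log2 change above 0 (median 1.01) and 14 had both LL libraries above both LH libraries; 10 had an unadjusted p under 0.05, 0 passed in edgeR and 0 with DESeq2. In fibroblast-like cells of LH replicate 2, with 93018 UMIs, HLF, TEF and NR1D1 had 10.0, 0 and 20.0 CPM. These values lay under the floor of 3 counts, so that library told little about them. DBP, a transcription factor with a daily rhythm, had 63.0 and 70.0 CPM in LH and 152 and 124 CPM in LL in fibroblast-like cells. BMAL1 and NFIL3, which peak at another time of day, had a median log2 change of -0.36, with 8 of 11 values under 0, so if the pattern is real, a time of collection that differed between stages may be its cause and cannot be told apart from the stage. The ratio of DBP to HLF differed between groups by 17.1 times in LL replicate 2 and 25.8 times in LL replicate 1. It differed in LH replicate 1 too: DBP and HLF had 41.4 and 2.07 CPM in the EDNRA/IGFBP7-high group. In T cell-like cells of that library they had 6.88 and 7.87 CPM. The ratio thus follows levels of the cell groups present in both stages, and it cannot decide whether free RNA of 1 cell type added to the LL values.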
